A study of Leucoraja erinaceus with 3 samples.

How the data were processed

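Single nuclei from dorsal root ganglia (DRG) and spinal cord of little skate embryos at stages 31 and 32 were analysed from deposited count tables. Per the labels, ganglia of 14 embryos were dissected individually and snap-frozen, and about 45000 DRG nuclei were loaded across 2 libraries, while about 60000 nuclei from spinal cords of 6 embryos went into 1 library. The values deposited by the authors are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode in tables already filtered to barcodes taken as cells. They were analysed as they stand, but are unlikely to be untouched counts, because in the DRG tables some abundant genes lack barcodes with 1 UMI (COX1, COX2 and map1aa in replicate 1, palm1a in replicate 2). This is the pattern that a removal of background before deposit would leave, and whether one was made is not given in the sources used here. Background levels, mitochondrial shares, low counts of abundant genes and the profile of discarded barcodes may therefore be too low or altered in the DRG libraries. STAR, STARsolo and Seurat 5.1.0 are named per the submitters' processing notes. The tables hold 22111 features, of which 12253 carry a locus number in place of a symbol, 21518 were found in the RefSeq gene table and 13 are mitochondrial genes. Another 24 features name no gene, held 2.21% and 3.09% of UMIs in DRG replicates 1 and 2 and 0.0363% in the spinal cord, and stayed out of all sums.

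The tables held 28252, 19301 and 27600 barcodes with medians of 148, 294 and 761 UMIs. Barcodes were kept with at least 200 detected genes (8310, 9865 and 23015) and at most 5% of UMIs on mitochondrial genes, which took out 1674, 2380 and 4. Doublets were called with Scrublet at an expected rate of 8%, which called 3, 2 and 0 nuclei and so has not worked, and doublets remain in all results. This left 23.5%, 38.8% and 83.4% of barcodes and 62.7%, 69.7% and 98.4% of UMIs. Counts were scaled to 10000 per nucleus and log-transformed, and the 2000 most variable genes were scaled within library (values limited to 10) and reduced to 30 principal components. Nuclei were clustered on 15 neighbours with the Leiden method (resolution 1, seed 0), the DRG libraries together and the spinal cord alone. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

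Marker genes, gene lists, comparisons and 36 alternatives were fixed before the data were examined. Symbols were matched without regard to case, exactly or with a final a, b, -like or _1, and 128 of 253 cell type markers, 66 of 121 neuron subclass markers and 234 of 409 list genes found a feature. A cluster was named where at least 3 markers of a class, each with at least 10 UMIs, stood at least 3-fold above the other clusters. Neuron clusters needed at least 3 pan-neuronal markers at least 2-fold above the named non-neuronal clusters, with the median ratio of non-neuronal markers to all nuclei at most 0.8. Leading genes were those with the largest fold among genes in at least 20 nuclei and 5% of the cluster. A cluster stayed unnamed if it held under 20 nuclei or if a mitochondrial or ribosomal gene was among its 15 leading genes. A non-neuronal name was also barred if another class had as many markers among the 10 leading genes, or if the first gene led the best marker more than 10-fold. Neuron clusters were not held to this, and spinal cord clusters 10 and 12 (1281 and 518 nuclei) each have 1 marker of another class against 1 of their own there. Depth under 0.333 of the median also barred a name, unless a non-neuronal cluster had an own marker among the leading genes. This naming rule and its thresholds were set after the clusters had been seen and after the shares under some alternatives had been looked at. Subclusters of neuron-like nuclei were named at 2-fold with at least 5 UMIs per marker, and were barred from a name if another class had as many markers among the 10 leading genes. Subclusters with at least 2 non-neuronal markers among the 10 leading genes, or a mitochondrial or ribosomal gene among 15, were marked as mixed, by a rule that was changed once after its outcome was seen.

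Neuron-like nuclei of each library were summed, giving 3281938, 3984026 and 16329893 UMIs, and log2 ratios of CPM (counts scaled to a common total) of each DRG library over the spinal cord were taken with a prior count of 1. Counts of genes at least 4-fold apart in both DRG libraries, among genes with at least 50 UMIs, are counts of sizes and not of significance. For lists, members with at least 10 UMIs were measured, those at least 2-fold apart in both libraries were counted, and the list median was placed among 10000 random lists matched on mean expression in 20 bins. Genes were named by a fixed rule: genes of the planned comparisons, the members of each list with the most UMIs and with the largest and smallest ratios, and the 12 largest and 12 smallest ratios by the library nearer 0 among genes with at least 50 UMIs and a symbol, without mitochondrial or ribosomal genes. Where a sum held 0 UMIs, a floor of 3 counts gives a bound.

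Shares of nuclei carry exact Clopper-Pearson intervals and sums exact Poisson intervals, both at 95%, and both cover counting error only. The background of a gene was read in a class taken to lack it. Depth was matched by drawing 300 UMIs from each nucleus without replacement, a number chosen after the data were seen, and nuclei with fewer were left out. Codetection is the number of nuclei with both genes over that expected of independent genes within 10 bins of nuclei by UMI count. Of 10 pairs, 3 were fixed before, and the calca pairs and all 4 spinal cord pairs were chosen after the data were seen. So were the DRG genes prdm12b, isl1a, drgx, etv1, shox2 and kcnk18, 8 added alternatives (mixed subclusters left out, only nuclei with at least 1000 UMIs, and 1 DRG library at a time for glia) and the values with which the account of the alternatives opens.

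The comparison was tested on simulated data, in which the sums of the 3 libraries were drawn from the profile of spinal cord neuron-like nuclei and 25 genes per size were changed in the DRG sums. Of the genes changed 8-fold, 25 of 25 higher and 23 of 25 lower ones were called, of those changed 4-fold 4 and 7, of those changed 16-fold 25 and 24, of those changed 2-fold 0, and of 14222 unchanged genes 0. The simulated sums hold counting noise only, without differences between libraries in background RNA or cell makeup. They therefore do not give the rate of false calls in the real comparison. Independent simulated genes had a codetection ratio of 1.01 ± 0.0326 (SD) over 20 draws. The alternatives changed the filter on genes (400 or 100), doublet removal, the resolution (0.5 or 2), joint clustering, the size factors, the UMI floor (10 or 200), the prior count (5), thinning, the bins of the codetection and the DRG library used. Left out were the planned codetections with slc17a6, the split into excitatory and inhibitory neurons and the pairs with ntrk3, for which no feature of that name was found. Results for some genes are not reported here.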

Results

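The series asked how the identity of sensory neurons relates to the layout of touch and body-sense circuits in the little skate (Leucoraja erinacea), a cartilaginous fish. Dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, and spinal cord were dissected from embryos of stages 31 and 32. Nuclei were profiled by single-nucleus RNA-seq in pre-templated instant partitions, droplets that each hold a barcoded bead, and molecules were counted by unique molecular identifiers (UMIs). The DRG group held 2 libraries from ganglia of 14 embryos, and the spinal cord group held 1 library from cords of 6 embryos. The count tables held 11071889 and 12267355 UMIs in DRG replicates 1 and 2 and 30674629 UMIs in the spinal cord library. After filtering, 6633, 7483 and 23011 nuclei were kept, with medians of 531, 616 and 902 UMIs and 375, 445 and 691 detected genes per nucleus. As far as the labels say, both DRG libraries came from 1 pool of embryos and may be technical replicates, and the spinal cord has no replicate. No test between the tissues was therefore possible. An SD (n = 2) is the spread between the DRG libraries. Intervals (95%, exact Clopper-Pearson for shares and exact Poisson for counts and ratios) cover counting error only.

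The first comparison was of the cell classes that each tissue yielded. Neuron-like nuclei, named from pan-neuronal genes such as elavl3, elavl4 and syt1a, made up 36.1% ± 5.55 (SD, n = 2) of kept DRG nuclei and 66.4% (interval 65.7 to 67.0) of spinal cord nuclei. Peripheral-glia-like nuclei, named from sox10, foxd3, egr2b and dhh, made up 13.7% ± 1.87 of DRG nuclei. These were 4 of 10 matched glial markers, while mpz, plp1a, pmp22b, fabp7b, mbpa and s100b did not pass. The 10 leading genes of the cluster held 0 glial markers, and prdm16, itpr3 and tgfbr3 led those with a symbol. The glial name is therefore weakly based. Cartilage-like nuclei, named from col2a1a, matn1, hapln1b, col9a1b and cnmd, made up 5.14% ± 0.634. These glial and cartilage shares depended on the processing: under the alternatives they ranged from 8.59% to 34.3% and from 0.530% to 5.63%, and with the 5 DRG nuclei that Scrublet called left in, they were 29.4% and 0.530%. In the spinal cord, 5.41% of nuclei were cycling-progenitor-like, 4.41% radial-glia-or-astrocyte-like, and 3.74% oligodendrocyte-like, the first falling to 3.32% at resolution 2. Another 0.939% were ependymal-like, 0.830% endothelium-like and 0.348% fibroblast-or-meninges-like. Within the DRG, replicate 1 held more neuron-like nuclei (40.1%, interval 38.9 to 41.2) than replicate 2 (32.2%, interval 31.1 to 33.3) and fewer peripheral-glia-like nuclei (12.3% against 14.98%). Clusters left unnamed held 42.9% and 47.2% of nuclei in the DRG libraries and 18.0% in the spinal cord, or 20.5% (mean) and 26.9% with a filter of 100 genes. The largest unnamed clusters carried pan-neuronal markers at least 2-fold above named non-neuronal clusters. In the DRG, clusters 3, 4 and 0 (2943, 1659 and 641 nuclei) had 3, 6 and 5 of them. In the cord, clusters 0 and 3 (2564 and 1070 nuclei) had 5 and 6, against 5 in the endothelium-like cluster. Non-neuronal markers, or mitochondrial or ribosomal leading genes, barred these unnamed clusters from a neuron name. Smaller unnamed clusters included a DRG cluster of 259 nuclei with the muscle genes casq2, ttn.1, myoz1a and mybpc1 and a DRG cluster of 380 nuclei with rhag and hmbsb, genes of red blood cells, among its leading genes. A spinal cord cluster of 75 nuclei had among them pkd2l1, a channel of neurons that contact the cerebrospinal fluid. The rule that named clusters was set after the clusters were seen. Shares were not read as differences in tissue makeup, because loading and dissection differed between the tissues.

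**Figure D1:**
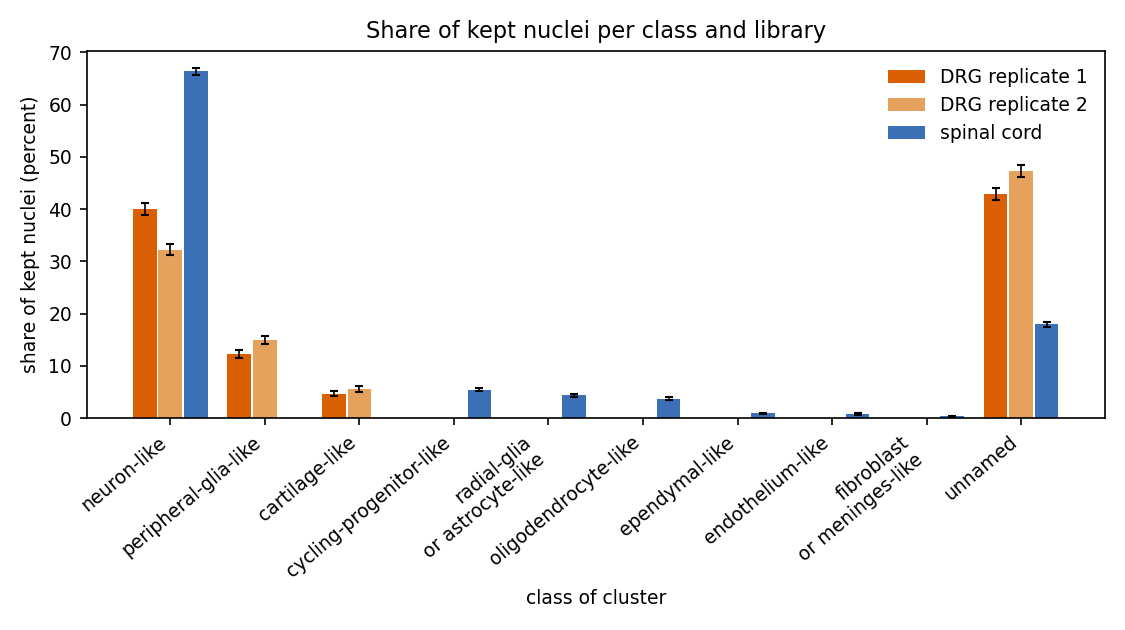
Bars give the share of kept nuclei (percent, y axis) in each class of cluster (x axis) for the 3 libraries, and error bars are exact Clopper-Pearson 95% intervals that cover counting error only. Neuron-like nuclei made up 40.1% and 32.2% of the DRG libraries and 66.4% of the spinal cord library, and unnamed clusters 42.9%, 47.2% and 18.0%.

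The DRG libraries were compared with each other before they were averaged. Across 14544 genes, log2 CPM (counts scaled to a common total per library) of all kept nuclei had a Pearson correlation of 0.977 and a Spearman correlation of 0.980, where genes are not independent replicates. In neuron-like nuclei the correlations were 0.974 and 0.971, and 189 genes (1.59%) differed by more than 2-fold. The counts differed by more than sampling noise (chi-square per degree of freedom 3.97 in neuron-like nuclei and 10.5 in all kept nuclei). Low counts of some abundant genes were missing from the DRG tables: in replicate 1, COX2 was present in 11733 barcodes and map1aa in 5260, and none of them held 1 UMI of the gene. In replicate 2, 1848 of 12552 and 2230 of 9348 barcodes did. Among genes in at least 1000 barcodes, 43 of 1480 in replicate 1, 3 of 1890 in replicate 2 and 0 of 5301 in the cord had fewer barcodes with 1 UMI than with 2. Of the genes at least 4-fold higher in DRG neuron-like nuclei these were 11 and 1, and of those lower 0. In replicate 1 they included the pan-neuronal markers stmn2b (458 barcodes with 1 UMI against 1545 with 2), nrxn1a (244 against 1226) and gap43 (663 against 1548). Of these only nrxn1a was among the 6 markers that named each DRG neuron-like cluster. The effect on the naming was not tested. A cluster rich in palm1a, which codes for a paralemmin, a protein attached to the inner face of the plasma membrane, held 9 nuclei of replicate 1 and 315 of replicate 2 and stayed unnamed. Other genes led it too, among them LOC129705127, marchf1, wdr6 and arhgap25 (3063-, 691-, 434- and 364-fold above the other DRG nuclei).

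The comparison of DRG and spinal cord neuron-like nuclei asked what sets sensory neurons apart from the neurons of the cord. Both ratios of a gene share the same cord sum. The SD of the ratios therefore leaves out the counting error of that sum, which is large where the cord holds few UMIs. Among the 12 genes with the largest ratios, the T-box transcription factor gene tbx2b stood first, with a log2 ratio (mean ± SD, n = 2) of 7.53 ± 0.12. Other transcription factor genes among them were tbx3a (5.87 ± 0.04) and isl2a (4.76 ± 0.07), a LIM-homeodomain factor of sensory and motor neurons. The ectonucleotidase gene entpd3 (7.01 ± 0.28), the background potassium channel gene kcnk18 (6.68 ± 0.05) and the cadherin gene cdh31 (5.91 ± 0.22) were also among them. The corepressor gene skor2 stood at 726 and 724 CPM in the DRG libraries and 29.0 CPM in the cord. The gene xirp2a, which codes for an actin-binding protein, stood at 355 and 434 CPM against 9.61 CPM. Among the 12 genes with the smallest ratios, log2 ratios were -5.31 ± 0.06 for nlgn1, a postsynaptic adhesion protein, -4.95 ± 0.34 for the potassium channel gene kcnd2, -4.45 ± 0.16 for the metabotropic glutamate receptor gene grm5b and -5.66 ± 0.72 for nxph1, a secreted ligand of neurexins. By the library nearer 0, the smallest ratio was that of ajap1 (-6.17 ± 0.07; 9.14 and 8.53 CPM against 657 CPM), and the transcription factor gene bcl11aa stood at -4.82 ± 0.09.

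Several of the 24 genes that the rule named by size rested on few molecules or were shared with other cells. The homeobox gene hmx4 had 1 UMI in spinal cord neuron-like nuclei, which gave ratios of 154 (interval 25.7 to 6286) and 160 (27.0 to 6474). Likewise cebpd had 3 UMIs there, with ratios of 202 (67.6 to 995) and 69.7 (22.5 to 349). The zinc finger gene sall3b had 10 and 2 UMIs in the DRG libraries (ratios 0.0214 and 0.00353, intervals 0.0103 to 0.0395 and 0.000427 to 0.0128). The synaptic organiser gene cbln1 had 1 and 7 UMIs (0.00715 and 0.0412, intervals 0.000181 to 0.0400 and 0.0165 to 0.0854), and prdm8b had 1 UMI in each (0.0197 and 0.0163, intervals 0.000498 to 0.111 and 0.000410 to 0.0915). The LIM-homeodomain gene lhx9 had 0 UMIs in replicate 1, at least 21.8-fold lower with a floor of 3 counts per library, and 2 UMIs in replicate 2, a ratio of 0.0252 (0.00304 to 0.0919). No UMI of slc18a3a, the vesicular acetylcholine transporter, was counted in DRG neuron-like nuclei (at least 6.90- and 8.38-fold lower), nor of the somatostatin gene sst1.1 (at least 14.5- and 17.6-fold lower). In the cord sst1.1 and sall3b were higher in named non-neuronal nuclei (23.8 and 353 CPM) than in neuron-like nuclei (13.3 and 142 CPM). In the DRG, tbx2b stood at 137 and 120 CPM in named non-neuronal nuclei against 144 and 128 CPM in neuron-like nuclei. The calcium-binding protein gene s100b, abundant in glia, stood higher outside neurons (115 and 126 CPM) than in them (71.9 and 71.0 CPM). For id1, an inhibitor of differentiation factors, non-neuronal nuclei had 105 and 45.1 CPM and neuron-like nuclei 75.3 and 62.8 CPM.

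Of 14995 genes with at least 50 UMIs, 462 were at least 4-fold higher in DRG neuron-like nuclei in both libraries and 295 were at least 4-fold lower, so 61.0% of these genes were higher. The median log2 ratio of all genes was 0.31 and 0.24 in the libraries. Median-of-ratios size factors moved every log2 ratio by -0.37 and -0.29 and turned the split to 289 higher and 399 lower (42.0% higher). With a floor of 10 or 200 UMIs, 713 or 300 genes were higher. No gene passed 4-fold in opposite directions in the DRG libraries, and 481 genes passed it in 1 library only. The former says little, because both ratios share the cord sum. Only 13 genes differed by more than 4-fold between the neuron-like sums of the DRG libraries. Of the 462 higher genes, 147 had a higher CPM in named non-neuronal than in neuron-like DRG nuclei in both libraries, and 56 of the 295 lower genes did so in the spinal cord. In the DRG the class lay in clusters 2 (2082 nuclei, median 2248 UMIs) and 5 (2985 nuclei, median 401 UMIs), and in the spinal cord in clusters 5, 8, 9, 10, 11, 12, 13, 14, 16 and 19.

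Lists of regulatory and transmitter genes, fixed before the data were examined, differed in how far they stood apart. Of 12 measured sensory lineage transcription factors, 10 were at least 2-fold higher in DRG neuron-like nuclei in both libraries and 0 were lower. Among the 10, prdm12b was no higher in DRG neuron-like than in glia-like nuclei (mean 4.39 against 4.90 CPM). The higher ones included shox2 (log2 4.17 ± 0.43), isl1a (3.39 ± 0.10), runx3 (3.23 ± 0.06), runx1 (3.09 ± 0.03) and tlx3b (2.01 ± 0.14), while etv1 stood at -0.70 ± 0.43. The list median of 3.16 lay 2.89 above that of all genes and at percentile 100 of 10000 random lists matched on expression. Of 27 spinal interneuron and motor neuron transcription factors, 13 were lower, including foxp2 (-3.57 ± 0.16) and zfhx3b (-1.07 ± 0.01), and only onecut1 was higher (2.31 ± 0.04). The median of this list was -1.23, at percentile 0. All 5 measured genes of inhibitory transmission were lower. They were gad2, which makes GABA (-3.49 ± 0.74), the glycine transporter genes slc6a5 (-4.31 ± 0.13) and slc6a9 (-3.12 ± 0.02), and the GABA transporter genes slc6a1b (-2.71 ± 0.15) and slc6a11b (-2.06 ± 0.03). In the cord, slc6a9, slc6a1b and slc6a11b had higher CPM in named non-neuronal nuclei (1100, 565 and 770 CPM) than in neuron-like nuclei (461, 256 and 106 CPM). Of 5 genes of neurofilaments and the peripheral cytoskeleton, neflb (2.79 ± 0.07), sncga (1.82 ± 0.13) and map1b (1.67 ± 0.10) were higher and none was lower (median 1.67, percentile 99.8). Size factors ended no call of these 4 lists and added 2 lower genes to the spinal list. In the DRG, neflb and map1b had higher CPM in named non-neuronal than in neuron-like nuclei.

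Lists of receptors, adhesion molecules and guidance genes were measured in the same way. Of 7 ionotropic glutamate receptor genes, grin2aa (-3.92 ± 0.27), grin3a (-3.80 ± 0.23) and grik1a were at least 2-fold lower (list median -0.85, percentile 1.09). Of 8 GABA and glycine receptor genes, 4 were lower, including gabrb1 (-2.33 ± 0.08) and glra2 (-1.70 ± 0.02; list median -1.14, percentile 0.0700). Of 19 synaptic and axonal adhesion genes, 5 were lower, including nlgn1 and tenm1 (-1.35 ± 0.07), and 3 were higher. Of the higher ones, the axonal adhesion gene cntn2 had 807 and 889 CPM against 55.5 CPM in the cord (list median -0.88, percentile 0.0200). With size factors, 4, 5 and 11 genes of these lists were lower and the adhesion gene nfasca was no longer higher. Of 17 axon guidance receptor genes, 6 were lower, including the netrin receptors unc5a (-3.39 ± 0.09) and dcc (-2.01 ± 0.06; list median -0.26, percentile 6.20). Another 2 were higher, plxna4 (1.67 ± 0.22), a receptor subunit for semaphorins, and unc5b, the latter only without size factors. Of 23 axon guidance ligand genes, 4 were higher, including ntng1a (2.89 ± 0.29), and 4 lower, including slit2 (-1.47 ± 0.05) and ntn1a (-1.90 ± 0.30). The median of 0.29 (percentile 61.5) turned to -0.04 with size factors, which also ended the calls of sema4c and sema4f.

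Sensory channels and peptides did not move together. Of 12 somatosensory ion channel genes, kcnk18, trpm2, cacna1ha and trpv4 were at least 2-fold higher, the last only without size factors, and the acid-sensing channel gene asic2 was lower (-1.54 ± 0.02; list median 0.36, percentile 73.0). Of 10 neuropeptide genes, calca, which codes for calcitonin gene-related peptide, had 195 and 191 CPM in the DRG libraries against 13.8 CPM in the cord (3.80 ± 0.02). The substance P precursor gene tac1 (1.17 ± 0.17) and nmba were also higher, tac1 only without size factors. The enkephalin precursor gene penkb (-2.37 ± 0.74), ccka and trh were lower, and the list median of 0.24 (percentile 33.9; 0.62 and -0.24 in the libraries) turned to -0.09 with size factors. Of 6 neurotrophin and GDNF family receptor genes, 0 were higher and gfra4a and met (-1.78 ± 0.20) were lower (median -0.15, percentile 15.9). In that list, ntrk2a, the receptor of brain-derived neurotrophic factor, had 769 and 723 CPM against 373 CPM (1.00 ± 0.06), and ret, the GDNF receptor kinase, stood at 0.93 ± 0.08, each short of 2-fold in at least 1 library. The vesicular glutamate transporter slc17a8 was the only measured glutamatergic gene (1.51 ± 0.31, from 19, 17 and 29 UMIs). Its level in neuron-like nuclei (5.79, 4.27 and 1.78 CPM in DRG replicates 1 and 2 and the cord) was that of named non-neuronal nuclei in replicate 2 (4.26 CPM) and near it in the cord (1.67 CPM), and above it in replicate 1 (2.45 CPM). Of 9 cholinergic and monoaminergic genes, the serotonin-synthesis gene tph1a was higher (1.91 ± 0.72) and chata, slc18a3a and slc18a2 were lower (median -0.05, percentile 5.50). Of these, chata, which makes acetylcholine, had 3 and 5 UMIs in the DRG libraries (ratios 0.0357 and 0.0490, intervals 0.00733 to 0.105 and 0.0158 to 0.115).

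**Figure D2:**
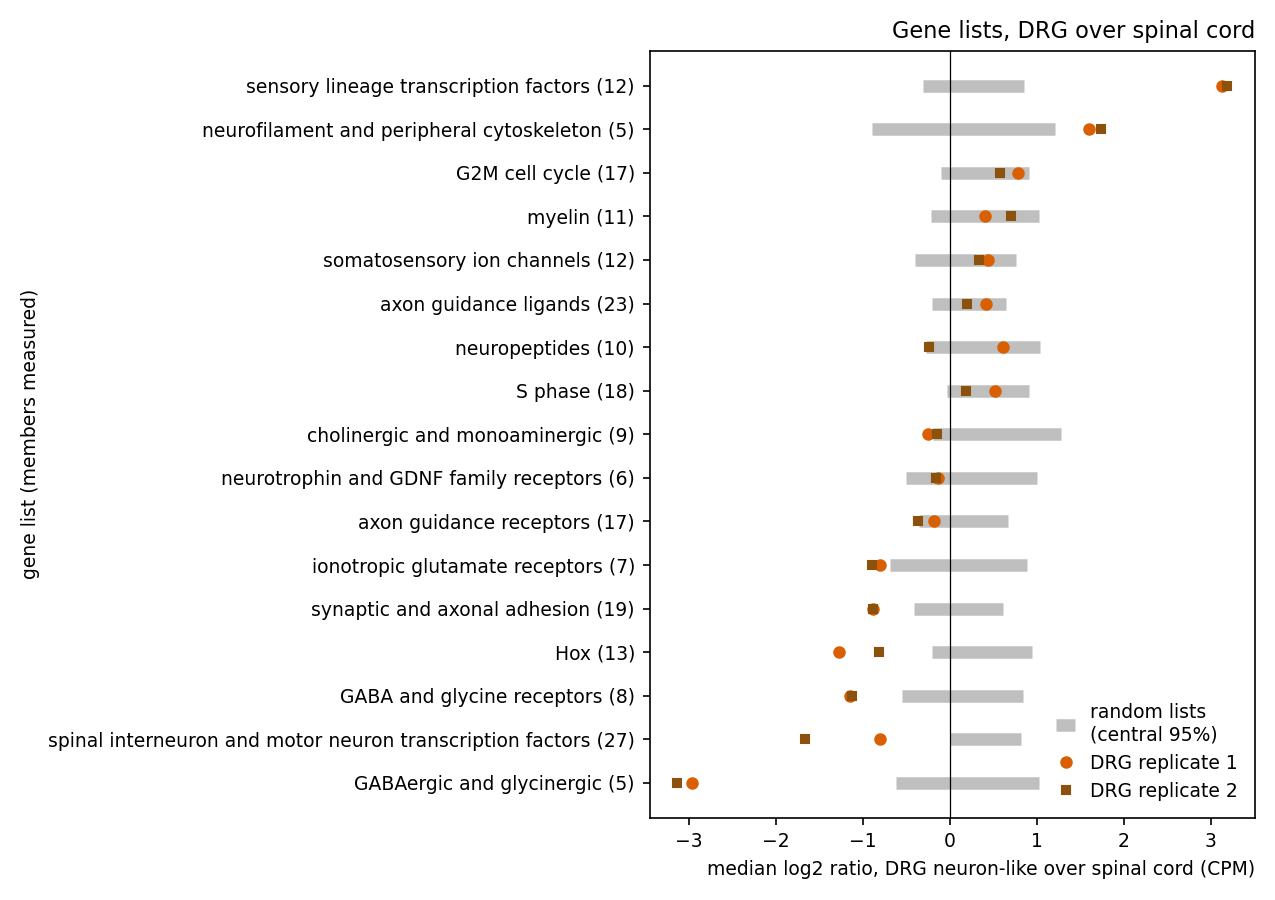
Points give the median log2 ratio of CPM (x axis) of each gene list with at least 5 measured members (y axis) in neuron-like nuclei of each DRG library over those of the spinal cord, and grey bars span the central 95% of 10000 random lists matched on expression. Sensory lineage transcription factors had a median of 3.16 and GABAergic and glycinergic genes of -3.12, and size factors turned the medians of the neuropeptide, axon guidance ligand and S phase lists from above to below 0.

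The next question was which sensory subclasses the DRG neuron-like nuclei held. The receptor gene ntrk2a, known from touch receptors, was detected in 31.8% and 37.3% of neuron-like nuclei (mean 34.6% ± 3.86, n = 2), calca, known from peptide-containing pain receptors, in 15.2% ± 3.89, and runx3, known from muscle-sense neurons, in 8.18% ± 2.10. Lower shares had ret (6.11% ± 0.924), tac1 (4.45% ± 1.34) and runx1 (4.44% ± 1.06), a factor of small-diameter pain receptors. Peripheral-glia-like nuclei were read as background, though expression of their own was not excluded. They had ntrk2a in 4.82%, calca in 2.38%, runx3 in 1.18%, tac1 in 0.712%, runx1 in 0.679% and ret in 0.395% of nuclei. Their medians were 529.5 and 581 UMIs, against 542 and 1038.5 UMIs in neuron-like nuclei. Thinning every nucleus to 300 UMIs left 2312 of 2657 and 2135 of 2410 neuron-like and 758 of 818 and 1020 of 1121 glia-like nuclei. The shares were then 15.4% against 1.38% for ntrk2a, 5.56% against 0.835% for calca and 2.41% against 0.477% for runx3. They were 2.07% against 0.247% for ret, 1.59% against 0.313% for tac1 and 1.06% against 0.262% for runx1. In neuron-like nuclei with at least 1000 UMIs, ntrk2a was detected in 55.4%, calca in 26.4%, runx3 in 14.99%, ret in 11.2%, runx1 in 8.64% and tac1 in 7.98%. Cartilage-like nuclei carried more of this background, with ntrk2a in 11.6% and 16.03% and calca in 4.82% and 7.42% of nuclei.

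Among genes chosen after the data were seen, isl1a was detected in 26.1% ± 7.66 of DRG neuron-like nuclei against 2.82% of glia-like nuclei, shox2 in 9.19% ± 4.85 against 0.662%, kcnk18 in 4.66% ± 1.80 against 0.590% and drgx in 2.86% ± 0.644 against 0.585%. For prdm12b (0.637% against 0.345%) and etv1 (1.43% against 1.11%) the share lay near that of glia, and the mean CPM was no higher in neuron-like than in glia-like nuclei (4.39 against 4.90 and 13.3 against 19.5). Unnamed DRG nuclei carried ntrk2a in 22.9% and 23.8% and calca in 10.3% and 8.77% of nuclei, above the level of glia. For runx1 their share was 2.28% and 7.10%, the latter above that of neuron-like nuclei (5.19%), and for tac1 it was 4.18% and 3.99% against 3.50% and 5.39%. The shares therefore describe the named neuron-like nuclei and not all neurons of the ganglion. Of the 15 subclass genes planned, 9 found no feature of that name, among them ntrk3, piezo2, trpv1 and pvalb. None of the 11 subclusters of DRG neuron-like nuclei could be named. In a subcluster of 711 nuclei (12.8% and 15.4% of neuron-like nuclei), the peptidergic pain receptor markers prdm12b, calca and tac1 stood 4.29-, 2.80- and 2.36-fold and the muscle-sense marker runx3 3.22-fold above the other neuron-like nuclei. It stayed unnamed because both classes had 1 marker among its 10 leading genes.

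**Figure D3:**
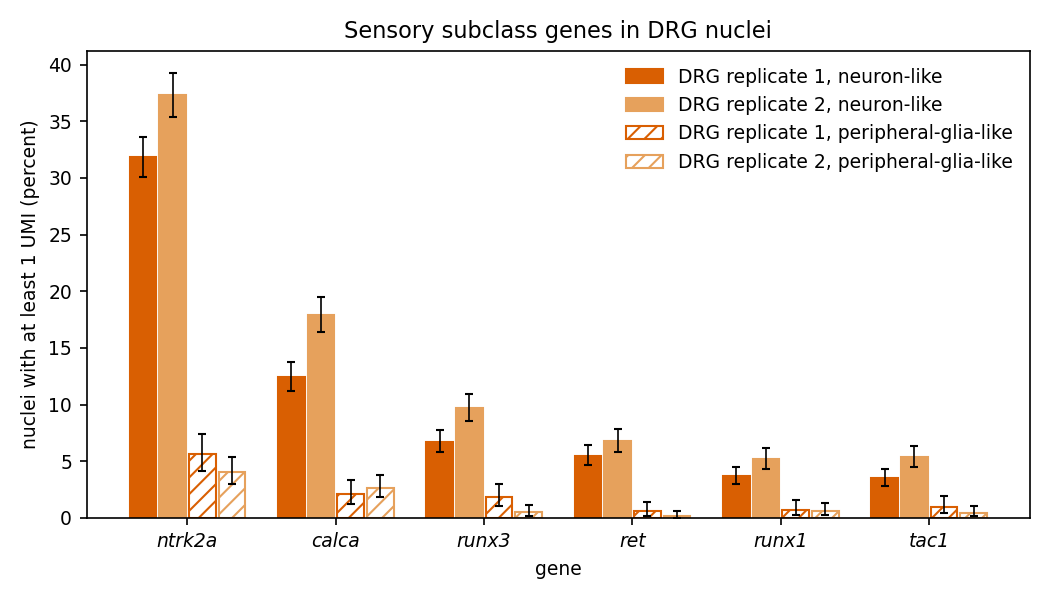
Bars give the percent of nuclei with at least 1 UMI (y axis) of 6 sensory subclass genes (x axis) in neuron-like (filled) and peripheral-glia-like (hatched) nuclei of each DRG library, and error bars are exact Clopper-Pearson 95% intervals that cover counting error only. Each gene was detected in a larger share of neuron-like than of glia-like nuclei in both libraries, with the largest shares, 31.8% and 37.3%, for ntrk2a.

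Pairs of these genes were then compared for how often they met in 1 nucleus. Detection of ntrk2a and runx3 in the same neuron-like nucleus fell short of that of independent genes, with 49 nuclei against 83.0 expected in replicate 1 (ratio 0.590, interval 0.437 to 0.780) and 48 against 117 in replicate 2 (0.411, interval 0.303 to 0.545). For ntrk2a and runx1 the ratios were 1.28 (0.991 to 1.63) and 1.10 (0.870 to 1.36), and for runx1 and runx3 they were 1.06 (0.550 to 1.86) and 0.525 (0.252 to 0.966). Among pairs chosen after the data were seen, calca met runx3 more often than expected (64 nuclei against 34.5 and 100 against 61.2; ratios 1.86 and 1.63), as did calca and tac1 (1.61 and 1.56), while calca and ret had ratios of 1.16 and 0.938. Expected numbers were taken within 10 bins of nuclei ranked by UMI count. Without the bins the ratio of ntrk2a and runx3 was 0.865 and 0.552, that of ntrk2a and runx1 was 2.12 and 1.74, and the mean of runx1 and runx3 turned from 0.795 to 1.33. Thinned to 300 UMIs, the mean of ntrk2a and runx3 was 0.258. The planned pairs with ntrk3 were not analysed here, because no feature bore that name.

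**Figure D4:**
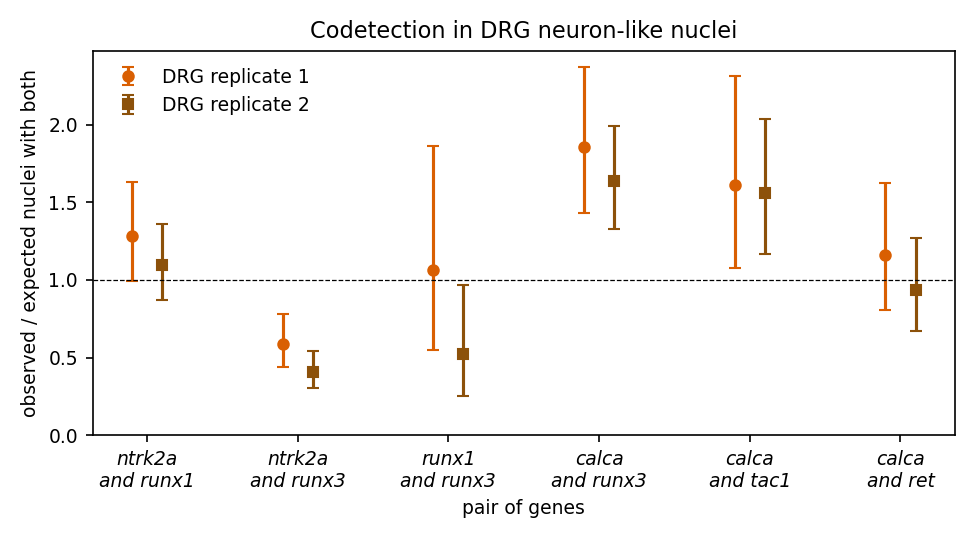
Points give the number of DRG neuron-like nuclei with both genes over the number expected of independent genes (y axis) for 6 pairs (x axis) in each library, with 95% Poisson intervals that cover counting error only and a dashed line at 1. The pair ntrk2a and runx3 lay at 0.590 and 0.411, below 1 in both libraries, and calca and runx3 at 1.86 and 1.63, above 1 in both.

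In the spinal cord, neuron classes were described from transmitter genes and class-defining transcription factors. The inhibitory genes gad2 or slc6a5 were detected in 20.9% (interval 20.3 to 21.6) of 15270 neuron-like nuclei against 5.24% (4.53 to 6.02) of 3608 named non-neuronal nuclei, at medians of 873 and 607.5 UMIs. Thinned to 300 UMIs (14723 and 3296 nuclei left), the shares were 7.80% and 1.33%. The cholinergic genes chata or slc18a3a were detected in 2.82% against 0.554% (thinned 0.706% against 0.182%; 5.76% in neuron-like nuclei with at least 1000 UMIs), where slc18a3a alone had 6.31 and 4.35 CPM in neuron-like and non-neuronal nuclei. The gene slc17a8 lay at the background level (0.190% against 0.139%). A motor-neuron-like subcluster, set apart by chata, slc18a3a, isl1a, isl2a and mnx1, held 1297 nuclei (8.49%). A dI1-like subcluster, named from barhl1a, barhl2 and lhx9, factors of a class of dorsal interneurons, held 511 nuclei (3.35%). The other 15 subclusters stayed unnamed.

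Class-defining transcription factors differed in how far they stood above background. In neuron-like against named non-neuronal nuclei of the cord, tlx3b was detected in 2.95% against 0.859%, uncx in 2.67% against 0.554%, isl1a in 2.37% against 0.499% and drgx in 1.82% against 0.471%. At lower shares stood lhx9 in 1.46% against 0.222%, lhx5 in 1.28% against 0.333%, isl2a in 1.11% against 0.0831%, wt1b in 1.05% against 0.333% and barhl2 in 0.943% against 0.194%. Shares of foxp2 (8.91% against 8.09%) and foxp1b (18.4% against 16.02%) lay nearer to those of non-neuronal nuclei, and that of gata3 (0.642% against 0.887%) lay below. The motor neuron marker aldh1a2, which codes for an enzyme, was detected in 2.60% against 5.18%. It was among the leading genes of the ependymal-like cluster, so its non-neuronal share is not background alone. All pairs of genes here were chosen after the data were seen. Both inhibitory genes met in 277 nuclei against 216 expected (ratio 1.28, interval 1.13 to 1.44), and chata and slc18a3a in 18 against 7.28 (2.47, 1.46 to 3.91). The gene gad2 met the excitatory-class factor tlx3b in 22 nuclei against 42.1 (0.522, 0.327 to 0.791) and chata at a ratio of 0.905 (0.665 to 1.20). The planned split into excitatory and inhibitory neurons was not analysed here, because slc17a6, gad1 and slc32a1 found no feature of their name.

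Glia of the ganglion and of the cord were compared for myelin and cell cycle genes. The 12 myelin genes together reached 1352 ± 90.1 CPM (n = 2) in peripheral-glia-like nuclei and 8314 CPM (interval 8118 to 8513) in oligodendrocyte-like nuclei, a log2 ratio of 2.62 ± 0.10. Neuron-like nuclei set the background at 328 and 323 CPM in the DRG and 258 CPM in the cord. In CPM the largest differences were those of mbpa, the myelin basic protein gene (322 and 327 CPM against 4206 CPM), and of sox10 (313 and 419.5 CPM against 1284 CPM), ahead of ugt8, myrf and mpz, though the fold of sox10 was the smallest of these 5. The gene sox10 also named the peripheral-glia-like cluster and the other 4 the oligodendrocyte-like cluster, so the list's difference follows in part from how the classes were drawn. Among genes that named neither class, pmp22b, a peripheral myelin protein gene, stood higher in peripheral-glia-like nuclei (120 and 155 CPM against 7.29 CPM from 6 UMIs), and drp2, a gene of the Schwann cell surface, at 59.8 and 54.0 CPM against 75.3 CPM, all below its level in neuron-like nuclei (101 and 94.4 CPM in the DRG and 117 CPM in the cord).

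Cell cycle genes set peripheral-glia-like nuclei apart from radial-glia-or-astrocyte-like nuclei of the cord. The 17 genes of the G2M list, active at mitosis, reached 1608 and 1791 CPM in the DRG libraries against 198.9 CPM (log2 3.09 ± 0.11, or 2.32 with at least 400 genes per nucleus). They reached 202.8 CPM in oligodendrocyte-like and 2579 CPM in cycling-progenitor-like nuclei, the latter named from genes of this list. Thinned to 300 UMIs (911 of 1014 radial-glia-or-astrocyte-like and 801 of 861 oligodendrocyte-like nuclei left), the G2M values were 1722 and 164.7 CPM. The myelin values were 1367 CPM in peripheral-glia-like and 10183 CPM in oligodendrocyte-like nuclei. The S phase list, of DNA replication genes, stood at 798 and 761 CPM in peripheral-glia-like against 275.6 CPM in radial-glia-or-astrocyte-like nuclei. Cycling nuclei of the cord formed a class of their own and those of the DRG did not, so the classes compared were not drawn alike. Between DRG and spinal cord neuron-like nuclei, 5 of 17 G2M genes, 3 of 18 S phase genes and 2 of 11 myelin genes were at least 2-fold higher and 0 were lower (medians 0.67, 0.16 and 0.39 at percentiles 85.1, 12.3 and 49.0). With size factors the S phase median was -0.17 and the calls of mcm5 and plp1a ended.

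Hox genes, which mark position along the body axis, were compared last. Only the 17 features with a Hox symbol entered the sums below. They were 7 genes of paralogue groups 1 to 6 (none of group 2), 3 of groups 7 to 9 and 7 of groups 10 to 13. Any Hox gene that carries a locus number is missing, so the sums are not totals of the paralogue groups. In neuron-like nuclei, Hox genes of paralogue groups 1 to 6 reached 112 and 119 CPM in the DRG libraries against 429 CPM in the cord, and those of groups 7 to 9 reached 51.8 and 56.5 CPM against 98.0 CPM. Those of groups 10 to 13 reached 1.83 (interval 0.671 to 3.98) and 2.51 (1.20 to 4.62) CPM against 18.4 (16.4 to 20.6) CPM. Among the genes measured, the last difference rests on hoxa10b, which holds 259 of the 301 UMIs in the cord. Of 13 measured Hox genes, 0 were at least 2-fold higher and 4 were lower, hoxb5a (-3.08 ± 0.09), hoxb6a (-1.87 ± 0.16), hoxd3a (-1.83 ± 0.01) and hoxa10b, which had 2 and 3 UMIs (ratios 0.0384 and 0.0475, intervals 0.00463 to 0.140 and 0.00973 to 0.140). The list median was -1.06, which was -1.34 relative to that of all genes, at percentile 0, and with size factors 8 genes were lower. In glia, the anterior groups 1 to 6 reached 94.9 and 67.8 CPM in peripheral-glia-like against 519.9 CPM in radial-glia-or-astrocyte-like and 175 CPM in oligodendrocyte-like nuclei. Groups 7 to 9 reached 96.7 and 31.4 CPM against 171 and 51.0 CPM, so that replicate 1 stood above oligodendrocyte-like nuclei there. The axial levels dissected are not given in the sources used here, so the Hox values describe the tissue as collected.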

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

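The tests of this part were set before their results were seen, except for the test of free palm1a RNA and the thinning to the depth of the palm1a-rich barcodes, which were chosen after. Features that name no gene held 2.21% and 3.09% of UMIs in DRG replicates 1 and 2 against 0.0363% in the spinal cord, a signal in data that the comparisons do not use. Among barcodes with fewer than 200 genes, which were left out of the comparisons, 4.88% and 11.9% in the DRG libraries and 0.305% in the spinal cord were rich in palm1a, with at least 5% of UMIs and 10 UMIs on this gene. These shares were noted because a signal stood above 0 in unused data, and neither difference between the tissues was tested.

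The cluster rich in palm1a held 4.21% of kept nuclei in DRG replicate 2 against 0.136% in replicate 1, while over all deposited barcodes 7.46% and 3.52% were rich in palm1a, a ratio of 2.12. If the lower depth of replicate 1 and the filter on genes were the cause, thinning the palm1a-rich barcodes of replicate 2 should leave shares within 2-fold, but the share passing the filter was still 4.39 times as large (interval 2.61 to 7.69, counting error only; 60 of 317 barcodes left in 1 random draw), against 23.2 times before. A value above 2 was to exclude depth, but that bound was wrong, because the thinning matched all barcodes and left the palm1a-rich ones deeper (median 147.3 against 119 UMIs), and at the latter depth the ratio was 1.61 (0.838 to 3.11; 22 barcodes left), so depth and a true difference cannot be told apart. Free palm1a RNA was to be excluded by a CPM in the cluster at least 10 times that in neuron-like nuclei (36436 times; 192058 against 5.27), but the cluster was picked for palm1a, and the 5.27 CPM, against 121 CPM in replicate 1, decide nothing where low counts are missing (0 of 1455 barcodes with 1 UMI, against 340 of 1680), so free RNA and cells that make palm1a cannot be told apart. The test used palm1a alone, though other genes led the cluster with it. Of these, LOC129705127 (19128 UMIs) and marchf1 (9557 UMIs) were found in 324 nuclei each, as was palm1a (39796 UMIs). Whether free RNA could hold these genes together was not tested. No biological explanation was tested, as the labels give no difference between the DRG libraries.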

How the results depend on the processing

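All 36 planned and 8 added alternatives ran, and no log2 ratio or codetection ratio past its threshold changed direction. Values near 0 did: the neuropeptide median ranged from -0.55 to 0.60 and kept its sign in 10 of 14 alternatives, mpz in 11, ache in 9, and the S phase and axon guidance ligand medians in 13. Shares and counts of genes were not checked for direction. The split of the 4-fold genes turned from 61.0% higher to 42.0% higher with size factors. No paired analysis was possible because the labels pair no DRG library with the spinal cord library. Of the values of 10 leading results under the alternatives, 54 stayed near the main value in size and 31 moved. Staying meant a change below the SD of the DRG libraries, a value inside the main interval, or a count of genes within a set fold. Calls were not compared. Using 1 DRG library alone always moves a mean by less than that SD, so such means stayed by arithmetic. For all other results 1393 stayed and 514 moved. Which values lead was chosen after the data were seen. The cause was not tested for the changes below except where the alternative itself sets it, as thinning and the UMI floors do. The main values stand in the report.

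With at least 400 genes per nucleus, neuron-like nuclei made up 42.8% of the DRG and 63.1% of the spinal cord, peripheral-glia-like nuclei 8.59%, nuclei with calca 20.9% and those with gad2 or slc6a5 23.1%, and the glial log2 ratios were 2.28 (myelin) and 2.32 (G2M). With at least 100 genes the glial share was 34.3%, the spinal cord neuron share 56.3%, calca 10.5%, gad2 or slc6a5 20.1%, myelin 2.72 and G2M 2.55. Without doublet removal these were 29.4% (glia), 2.79 and 2.44. Resolution 0.5 gave neuron shares of 44.6% and 67.2%, resolution 2 gave 61.4% in the spinal cord, and clustering each library alone gave a glial share of 15.6%. Genes at least 4-fold higher in DRG neuron-like nuclei numbered 289 with size factors, 713 with a floor of 10 UMIs and 300 with 200 UMIs. Thinning gave calca 5.56%, gad2 or slc6a5 7.80%, ntrk2a with runx3 0.258, myelin 2.90 and G2M 3.38; without bins the pair stood at 0.708. Nuclei with at least 1000 UMIs gave 26.4% (calca) and 28.0% (gad2 or slc6a5). With 1 DRG library at a time, 507 to 581 genes were higher and 347 to 390 lower, the pair lay at 0.411 to 0.590, myelin at 2.55 to 2.69 and G2M at 3.02 to 3.17. Depth limits the shares of nuclei, since fewer UMIs per nucleus detect fewer genes.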

Other observations

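The tests of this part were set before their results were seen, except for the scale on the highest marker and the values without mixed subclusters and with at least 1000 UMIs, which were chosen after. Motor-neuron-like nuclei of the skate cord carried the peptide gene calca at 13.2 times the level of other neuron-like nuclei of the cord, next to isl2a and the annexin gene anxa1a among the genes that led the subcluster. In mammals motor neurons also make the peptide that this gene codes for. The inhibitory genes gad2 and slc6a5 were also detected in 19.0% and 22.8% of unnamed spinal cord nuclei, whose median of 1870 UMIs was above the 873 UMIs of neuron-like nuclei. Thinned to 300 UMIs, the shares were 2.82% and 3.48% in unnamed and 2.91% and 5.14% in neuron-like nuclei, so the unnamed nuclei showed no excess over neuron-like nuclei. Named non-neuronal nuclei then had 0.425% and 0.910%, so the unnamed nuclei stood above that background.

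Mixed subclusters, with non-neuronal, mitochondrial or ribosomal genes among their leading genes, held 9.94%, 15.02% and 17.5% of neuron-like nuclei in DRG replicates 1 and 2 and the spinal cord. Without them 403 of the 462 genes (87.2%) stayed at least 4-fold higher and 275 of 295 lower. In nuclei with at least 1000 UMIs (863, 1225 and 6213), 350 of the 462 genes stayed (75.8%) and 270 of the 295.

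Detection of calca with runx3 in the same DRG neuron-like nucleus, at 1.86 and 1.63 times the expected number, may come from depth or mixed RNA that raises the codetection of any pair. Among 1000 random pairs per library matched on their shares of nuclei (within 20%), the value lay at percentile 100 in replicate 1 and 99.9 in replicate 2, above the central 95% of 0.833 to 1.32 and 0.853 to 1.20. These ranks decide little, because the pair was chosen after the data were seen. The random pairs had medians of 1.06 and 1.02, so a rise common to all pairs does not account for the excess. Mixed RNA that holds calca and runx3 together was not tested. If doublets among nuclei with many UMIs were the cause, nuclei under the median UMIs should show no excess. There the ratio was 1.77 (interval 0.944 to 3.03, counting error only; 13 nuclei against 7.34 expected), so doublets and shared expression cannot be told apart. No biological explanation was tested.

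The 462 genes higher in DRG neuron-like nuclei might carry RNA of non-neuronal DRG cells. After the profile of discarded barcodes (14243 and 4851 with fewer than 100 genes) was taken out, scaled on 6 glial and cartilage markers to 11.0% and 8.06% of UMIs, 384 of them (83.1%) stayed at least 4-fold higher in both libraries. Before the test, a result above 2 of every 3 genes was to exclude this cause, but that bound was wrong, because the markers themselves gave scales from 5.46% to 35.0% and from 2.43% to 19.6%, and with the highest marker only 286 genes stayed. The median change over the 462 genes was 0.01 in log2, and of those named by the fixed rule only runx1 was among the 78 lost (log2 3.09 before and 2.10 after), while the others stayed, s100b with the next largest fall (4.52 to 3.73) and skor2 with a rise (4.64 to 4.74). The removal shrank the DRG totals, which by itself raises the ratio of a gene that the profile lacks. The cord sum was not treated alike. A median change near 0 therefore does not show that little was removed, and the rescaling also helped genes to stay. Mixed RNA and expression in the neurons therefore cannot be told apart for many of these genes, and tissue and library also cannot be told apart, as the cord has 1 library.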
